A study of Mus musculus with 4 samples.

How the data were processed

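Chromosome conformation was measured by Hi-C in haematopoietic progenitor cells of the mouse, isolated from bone marrow by removing cells that carry lineage markers, per the labels' protocols. Hi-C joins DNA ends that lie close together in the nucleus and counts the joined pairs by sequencing. The libraries followed the Hi-C 2.0 protocol with the restriction enzyme DpnII, per the labels. There were 4 libraries, 2 labelled Stag2 wildtype and 2 labelled Stag2 knock-out. Groups were taken from the genotype label, and replicate numbers were given in accession order, so that they name libraries and pair none. All 4 titles carry R1, and the titles of replicate 2 of each genotype also carry the suffix T1, whose meaning the labels do not give. Each title also holds a number that differs between the libraries, and the labels do not say what it stands for. Nothing in the labels says whether the 2 libraries of a genotype came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

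The deposited values were insulation scores and compartment eigenvectors, both treated as a score. The scale of the eigenvector differed between chromosomes. Its SD was 0.0323 on chromosome 1 (955 bins) and 0.0594 on chromosome 19 (284 bins), alike in both genotypes. Its size is therefore not comparable between chromosomes and cannot show a change in compartment strength. Ranks, deciles and cutoffs of the eigenvector over the genome mix these scales. An insulation score compares the contacts that cross a bin with those of its surroundings, and its local minima mark domain boundaries. The log base of the insulation score and the size of the insulation window were not given in the sources used here. The authors deposited insulation scores of each single library in 20 kb bins, and 1 profile per genotype in 10 kb bins, per the file headers. The authors deposited the eigenvector as 1 profile per genotype in 200 kb bins, per the file headers. How libraries were pooled for the 10 kb and 200 kb profiles was not given in the sources used here. Coordinates are those of mm9, per the submitters' processing notes. The aligner, read filters and matrix balancing were not given in the sources used here. The deposited differences equalled knock-out minus wildtype in every bin within 1e-09.

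Read numbers per library were not given in the sources used here, so sequencing depth is unknown and no counting interval was computed. The number of scored bins stood in for it only as a description. Of 131957 bins of 20 kb, 117252 (88.9%) had a score in all 4 libraries and entered every comparison between genotypes, 11727 had none in any library and 2978 had a score in some libraries. The 10 kb profiles listed 227822 bins, all with a value in both genotypes, and the eigenvector listed 12398 bins. The 20 kb and 200 kb values covered 20 chromosomes, the 19 autosomes and X. The 10 kb profiles covered the 19 autosomes and 108 bins of Y, and listed 0 bins of X here.

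The test per bin was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on the mean score) on the deposited scores, with genotype as the only term and Benjamini-Hochberg adjustment over the 117252 bins at a threshold of 0.05. The design fixed before the data were examined had assumed single libraries at 10 kb. Single libraries were given at 20 kb, so the test was run at 20 kb. Called bins within 50 kb of each other that changed in the same direction were joined into regions. The rule for named regions, also fixed before the data were examined, took the 10 regions with the largest mean change in each direction among those of at least 3 called bins, leaving out regions within 1 Mb of the first or last scored bin of a chromosome. Values of a region are means over its called bins, so choosing the largest changes makes them larger on average than a repeat measurement would be. Where 200 kb bins changed sign between genotypes, the 5 with the largest eigenvector change in each direction were named, joined where adjacent. The limma step was tested on simulated scores of 117252 bins for the comparison of knock-out with wildtype. With 200 changed bins it recovered 3.70% of changes of 0.1, 70.4% of changes of 0.2 and 98.7% of changes of 0.4, and 13.1% of its 145 calls were false. With 23450 changed bins it recovered 39.8%, 96.2% and 99.99% of these sizes, and 4.27% of its 19310 calls were false. The simulated noise was independent between bins and the changed bins were placed at random. Real scores vary together over neighbouring bins, so these rates do not carry over to the real calls.

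The spread of a library was the SD of its scores across the 117252 bins. A running mean over 51 bins (1.02 Mb) separated broad from local variation. Boundaries were local minima, over 10 bins (200 kb) on each side, of the mean profile of all 4 libraries, with a depth of at least 0.2 below the mean of the highest flanking score on each side. Depth was then read at the same positions in each library. On simulated profiles this search found 18 of 18 boundaries planted with a depth of 0.3, 19 of 19 with a depth of 0.6 and 0 of 28 with a depth of 0.1, and 0 elsewhere. The planted dips were isolated and had little noise, and a depth of 0.1 lies below the threshold. These shares follow largely from the settings and do not give the accuracy on real profiles. Boundaries of separate profiles were matched within 40 kb. Each 20 kb bin took the eigenvector sign of the 200 kb bin that holds it in each genotype. Compartments are called positive and negative, since no gene density on mm9 was used here to name them. Comparisons of 1 value per library used a two-sided exact permutation test of 2 against 2 libraries, whose smallest possible p is 0.333, so that no such test could pass 0.05. Values across bins or chromosomes of the same libraries are not independent replicates. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

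Alternatives were each library left out in turn, the T1 suffix as a block, quantile normalization, scaling of each library to unit SD, eBayes without trend, autosomes alone, the mean of 5 bins (100 kb), a threshold of 0.1, other measures of spread, other boundary depths, windows and profiles, and a filter on small eigenvector values. Subtracting the running mean, limma on boundary depths, unit SD scaling at unchanged boundaries, crossed pairs and autosomes alone for the agreement between libraries, 10 kb profiles and all alternatives of the link between compartment and insulation except the filter on small eigenvector values were added after the data were examined. With a library left out, the lone library of its genotype was assumed to vary like the other genotype's. Gene lists fixed in advance were not analysed here, because the gene table used here gives GRCm38.p6 positions and the files use mm9. For the same reason no gene is named in any region, and the knock-out itself was not checked from these values.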

Results

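Hi-C profiles of lineage-depleted bone marrow progenitors of the mouse were compared between Stag2 wildtype and Stag2 knock-out, with 2 libraries per genotype. Stag2 encodes a subunit of cohesin, the ring-shaped complex that extrudes chromatin loops and holds them at CTCF sites. The comparison addressed how loss of the gene alters chromosome folding in blood progenitors. Insulation scores of single libraries described domains at 20 kb, and a compartment eigenvector of each genotype described the larger division of chromosomes at 200 kb. A low score marks a position that few contacts cross. Scores were present in 120151 bins of wildtype replicate 1, 118162 of wildtype replicate 2, 118759 of knock-out replicate 1 and 117486 of knock-out replicate 2. Sequencing depth was unknown.

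The insulation landscape was largely shared between genotypes, and the libraries of a genotype lay closer to each other than to the other genotype. Pearson's r across 117252 bins was 0.991 between the wildtype libraries and 0.987 between the knock-out libraries. Between genotypes r ranged from 0.966 to 0.971 over the 4 pairs. The SD of the bin-by-bin difference was 0.0577 between the wildtype libraries, 0.0761 between the knock-out libraries and from 0.113 to 0.117 between genotypes. The differences between genotypes repeated across libraries. The difference of knock-out replicate 1 from wildtype replicate 1 correlated with that of knock-out replicate 2 from wildtype replicate 2 with r = 0.637 and rho = 0.649 across bins. The crossed pairs gave r = 0.668.

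Insulation scores differed between knock-out and wildtype in many bins of the genome, in both directions and often in runs of neighbouring bins. Of the 117252 bins, 26308 (22.4%) passed limma's test at an adjusted p below 0.05. Of these, 13148 were higher and 13160 lower in knock-out. The called bins joined into 1041 higher and 1438 lower regions, of which 814 and 985 held at least 3 called bins. Those longer regions had a median length of 240 kb where scores were higher and 200 kb where they were lower, and the longest spanned 2100 kb and 2420 kb. The insulation window is unknown and neighbouring scores vary together, so these lengths do not give the extent of the underlying changes. The wildtype eigenvector was positive in 630 of 813 (77.5%) of the higher regions and in 236 of 981 (24.1%) of the lower regions that had a value. The median difference was 0.153 in bins called higher and -0.167 in bins called lower, against a median standard error of 0.0402. Over all bins the difference had a median of -0.00721, and 5% of bins lay below -0.175 and 5% above 0.163. The share of bins called per chromosome ran from 15.0% on chromosome 19 to 27.5% on chromosome 11. The number of calls fell to 9213 without wildtype replicate 1 and to 9445 without wildtype replicate 2. After a running mean over 1.02 Mb was subtracted from each library, limma called 0 bins, with 21852 at an unadjusted p below 0.05. In the regions named here the difference after subtraction was from 11.1% to 94.8% of its size before, with a median of 55.7%.

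Among regions with lower scores in knock-out, the largest change over all 4 libraries lay on chromosome 16 from 18980001 to 19240000 (mm9). That rank depended on the libraries used. Without knock-out replicate 2 its difference was -0.288, against -0.383 for the region of chromosome 6 from 67740001 to 68520000. Its 13 called bins averaged -0.285 ± 0.0241 in wildtype and -0.648 ± 0.105 in knock-out (SD, n = 2), a difference of -0.363. All 13 bins passed limma's test, with adjusted p up to 0.0210. On chromosome 6, 39 called bins from 67740001 to 68520000 fell from -0.0807 ± 0.0283 to -0.430 ± 0.0469 (SD, n = 2), with 9 bins unscored in at least 1 library inside the region or within 200 kb of it. A shorter region of the same chromosome, from 70420001 to 70540000, differed by -0.315 over 4 called bins, with 13 such unscored bins. That short region differed by -0.278 without wildtype replicate 1, where most of its bins no longer passed, and by -0.200 without knock-out replicate 1. The broadest of the 10 regions lay on chromosome 11 from 44440001 to 46060000, where 79 called bins over 1620 kb fell from -0.0345 ± 0.0374 to -0.321 ± 0.0280 (SD, n = 2). Both knock-out libraries, at -0.301 and -0.341, lay below both wildtype libraries, at -0.0609 and -0.00809. After the running mean was subtracted, the chromosome 11 region differed by -0.0317 and the longer chromosome 6 region by -0.0771. The lowest single bin on chromosome 11 differed by -0.490, and the 10 kb profiles differed by -0.213 over the same span. The eigenvector of the chromosome 11 region averaged -0.0143 in wildtype and -0.0234 in knock-out.

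The other 6 lower regions spread over 4 chromosomes. On chromosome X, scores fell by 0.331 from 142020001 to 142420000 and by 0.286 from 58480001 to 58940000, with 11 and 10 unscored bins in or near them. On chromosome 2, 23 bins from 43260001 to 43720000 went from -0.734 ± 0.0732 to -1.05 ± 0.0356 (SD, n = 2). On chromosome 3, 14 bins from 91560001 to 91840000 went from -0.496 ± 0.0392 to -0.799 ± 0.0646 (SD, n = 2). On chromosome 17, 6 called bins from 19080001 to 19200000 went from 0.334 ± 0.0433 to 0.0442 ± 0.179 (SD, n = 2). The knock-out libraries there were at -0.0822 and 0.170, and the difference of -0.290 became -0.164 without knock-out replicate 1. Another 3 called bins of chromosome 17, from 39600001 to 39700000, differed by -0.292, and 22 bins in or near them were unscored. Their wildtype libraries were at -0.301 and -0.0926, and without wildtype replicate 2 the difference was -0.188 and most bins no longer passed. The 10 kb profiles listed 5 of the 10 lower regions and were lower in knock-out in 5 of those 5. These profiles may rest on the same libraries, so this is not independent evidence.

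Over all 4 libraries, scores rose most in knock-out on chromosome 3 from 90200001 to 90560000. Its 18 called bins averaged -0.684 ± 0.0714 in wildtype and -0.319 ± 0.0547 in knock-out (SD, n = 2), a difference of 0.365. All 18 bins passed limma's test, with adjusted p up to 0.0280, and the highest single bin differed by 0.498. On chromosome 9, 36 called bins from 49580001 to 50300000 rose from -0.296 ± 0.0114 to -0.0224 ± 0.0345 (SD, n = 2). After the running mean was subtracted, that region differed by 0.0681. Its eigenvector averaged -0.0137 in wildtype and 0.00137 in knock-out. On chromosome 6, 26 called bins from 121000001 to 121520000 rose from -0.498 ± 0.0581 to -0.230 ± 0.0391 (SD, n = 2). On chromosome X, scores rose by 0.304 from 162360001 to 162640000 and by 0.294 from 93340001 to 93720000, each with 10 unscored bins in or near the region. The second of these went from -0.168 ± 0.0429 in wildtype to 0.126 ± 0.00605 in knock-out (SD, n = 2).

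On chromosome 10, scores rose by 0.284 from 107640001 to 107900000. Another region of chromosome 10, from 7180001 to 7240000, rose by 0.279 over 3 called bins from a wildtype mean of -1.86 ± 0.0354 (SD, n = 2). On chromosome 7, scores rose by 0.311 from 55840001 to 56000000 and by 0.274 from 31920001 to 32020000, the latter with 10 unscored bins in or near it. On chromosome 2, 6 called bins from 37140001 to 37260000 rose by 0.292, and the difference was 0.277 after the running mean was subtracted. Without wildtype replicate 1, most bins no longer passed in the short region of chromosome 10, at 0.254, or in chromosome 7 from 55840001, at 0.276, and from 31920001, at 0.226. The same held without wildtype replicate 2 for the short region of chromosome 10, at 0.304, and the region of chromosome 2, at 0.266. It also held without knock-out replicate 1 for chromosome 7 from 31920001, at 0.184. The 10 kb profiles listed 8 of the 10 higher regions and were higher in knock-out in 8 of those 8. As for the lower regions, this is not independent evidence. Unscored bins lay in or within 200 kb of 5 of the 10 lower and 3 of the 10 higher regions. By comparison, 2.82% of all single bins lie within 200 kb of an unscored bin. Regions span several bins, so these shares are not on an equal footing, but many named regions lie beside unscored sequence.

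**Figure D1:**
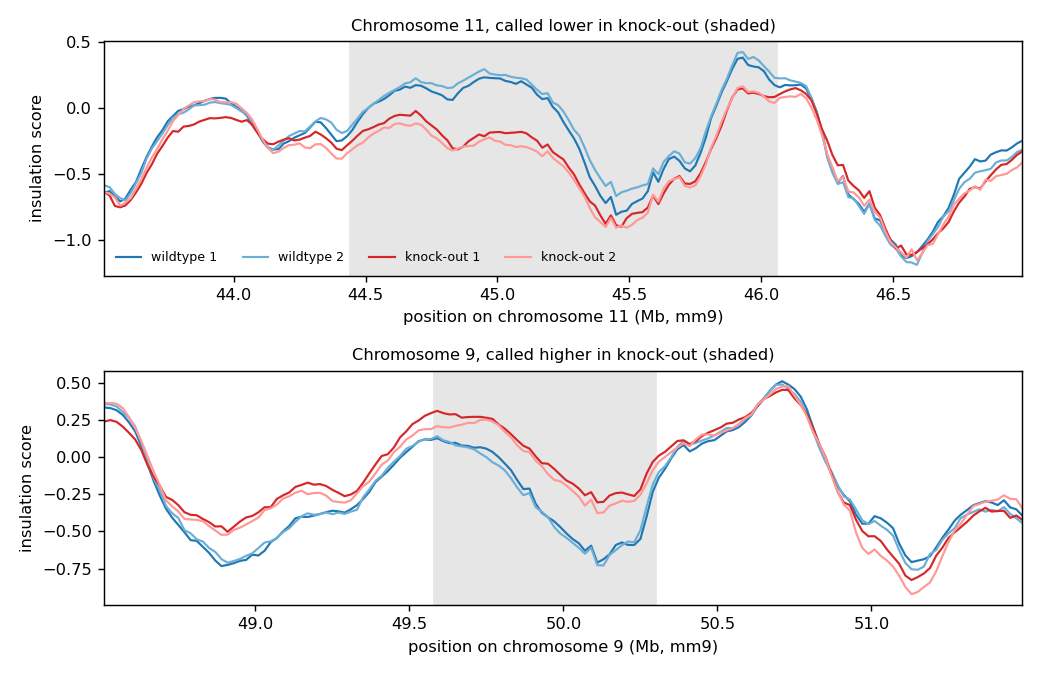
Insulation score (vertical axis, score units) of the 4 libraries along chromosome 11 and chromosome 9 (horizontal axis, Mb in mm9), with wildtype libraries in blue and knock-out libraries in red. Shading marks the regions called lower from 44440001 to 46060000 and higher from 49580001 to 50300000, where the means of both knock-out libraries over called bins lie below and above those of both wildtype libraries.

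Scores spread more widely along the genome in knock-out. The SD across bins was 0.435 ± 0.00428 in wildtype and 0.458 ± 0.00870 in knock-out (SD, n = 2), a difference of 0.0230. Both knock-out libraries, at 0.452 and 0.464, lay above both wildtype libraries, at 0.432 and 0.438. On single chromosomes the mean knock-out SD was higher on 20 of 20, and both knock-out libraries exceeded both wildtype libraries on 19 of them. The ratio of knock-out to wildtype SD ran from 1.004 on chromosome 13 to 1.08 on chromosome 15. The wider spread was in the broad component of the profiles. The SD of the running mean over 1.02 Mb was 0.306 ± 0.00617 in wildtype and 0.339 ± 0.00390 in knock-out (SD, n = 2). The SD of what remained after subtraction was 0.268 ± 0.00170 and 0.263 ± 0.00925 (SD, n = 2), a difference of -0.00508 that was smaller than the range of the knock-out libraries. The exact permutation test, two-sided, gave p = 0.333 for the SD and for the SD of the running mean, the smallest p that 2 against 2 libraries can give.

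Most domain boundaries of wildtype had a knock-out boundary nearby. Their mean depth in score units differed between genotypes by less than the range of the knock-out libraries. After scaling each library to unit SD, the difference at the same boundaries was -0.0979 SD, above the largest range within a genotype, 0.0464 SD. Part of that difference follows from dividing every depth by the larger SD of the knock-out libraries. At 1905 boundaries the mean depth was 0.447 ± 0.00643 in wildtype and 0.426 ± 0.0231 in knock-out (SD, n = 2), a difference of -0.0210. Knock-out replicate 1 had a mean depth of 0.409, whereas knock-out replicate 2, at 0.442, was level with wildtype replicate 2, at 0.442. Without knock-out replicate 1 the difference was -0.00625, and without knock-out replicate 2 it was -0.0389. The two-sided exact permutation test gave p = 0.333. By the mean of each genotype 1172 boundaries (61.5%) were shallower in knock-out. In single pairs of libraries the share ran from 49.3% for knock-out replicate 2 against wildtype replicate 2 to 70.8% for knock-out replicate 1 against wildtype replicate 1. Within a genotype, knock-out replicate 1 was shallower than knock-out replicate 2 at 70.8% of boundaries, and wildtype replicate 1 than wildtype replicate 2 at 40.7%. Both knock-out libraries lay below both wildtype libraries at 638 boundaries (33.5%) and above both at 290 (15.2%). Chance would give 16.7% each way only if the 4 libraries were exchangeable at each boundary. Knock-out replicate 1 was shallower than the other knock-out library at most boundaries, so these shares do not separate genotype from that library. Limma on the depths called 33 boundaries at an adjusted p below 0.05, of which 25 were shallower and 8 deeper in knock-out. That count fell to 0 without knock-out replicate 1 and to 0 without knock-out replicate 2, with 277 and 408 boundaries at an unadjusted p below 0.05. It fell to 7 without wildtype replicate 1 and to 10 without wildtype replicate 2.

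The difference among the deepest boundaries rested largely on knock-out replicate 1. In the deepest of 5 classes of 381 boundaries, the mean depth was 0.804 and 0.787 in the wildtype libraries and 0.718 and 0.775 in the knock-out libraries, and 70.9% were shallower in knock-out. The difference of -0.0485 in that class was smaller than the range of 0.0577 within knock-out. It was -0.0197 without knock-out replicate 1 and -0.0774 without knock-out replicate 2. In the shallowest class the depth was 0.236 and 0.237 in the wildtype libraries and 0.219 and 0.238 in the knock-out libraries. Of 1978 boundaries found in the mean wildtype profile, 1598 (80.8%) had a boundary of the mean knock-out profile within 40 kb. In the other direction 83.8% of 1907 knock-out boundaries had a wildtype boundary. Between the wildtype libraries 80.6% of the boundaries of replicate 1 and 83.6% of those of replicate 2 matched. Between the knock-out libraries 80.1% of those of replicate 1 and 75.2% of those of replicate 2 matched. Between single libraries of different genotypes the shares in both directions ran from 71.7% to 78.5%, which overlaps the shares within knock-out. Of all scored bins, 8.13% lay within 40 kb of a knock-out boundary. Where boundaries were taken from the knock-out profile alone, the share shallower in knock-out was 49.1%, against 72.3% where they were taken from the wildtype profile alone.

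**Figure D2:**
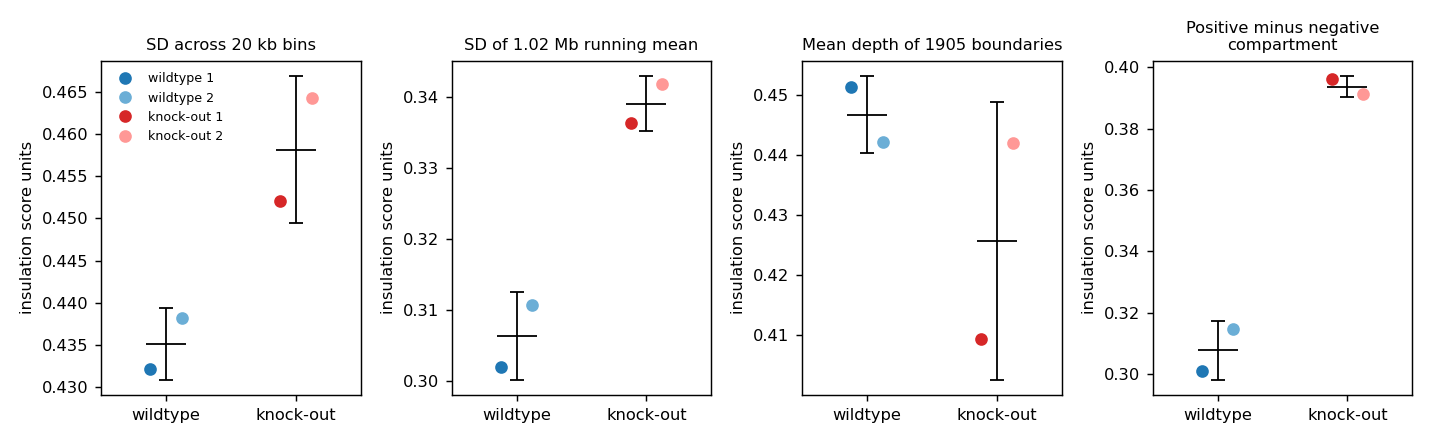
Each point is 1 library, horizontal lines are genotype means and bars are ± 1 SD (n = 2), all in insulation score units on axes that do not start at 0. Panels show the SD across 20 kb bins, the SD of the 1.02 Mb running mean, the mean depth of 1905 boundaries and the mean score of positive minus negative compartment bins, and the knock-out libraries lie above both wildtype libraries in all of these except boundary depth.

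The division of chromosomes into compartments was nearly the same in both genotypes. Pearson's r between the wildtype and the knock-out eigenvector was 0.995 over 12398 bins of 200 kb, and per chromosome it ran from 0.990 on chromosome 13 to 0.998 on chromosome 8. The sign differed in 262 bins (2.11%), of which 171 were positive in wildtype and negative in knock-out and 91 the reverse. These bins numbered from 7 to 23 per chromosome, with the most on chromosome 2. In 262 of the 262 the value lay within 0.01 of 0 in at least 1 genotype. The eigenvector came as a single profile per genotype, so none of these differences has a replicate check or a test.

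Eigenvector units differ in scale between chromosomes, so ranks across chromosomes are only descriptive. Among bins that turned negative in knock-out, the largest change in these units lay on chromosome 17 from 73800001 to 74000000, with 0.00335 in wildtype and -0.0234 in knock-out. Chromosome 13 from 9800001 to 10000000 went from 0.00724 to -0.0118, and chromosome 3 from 53600001 to 53800000 went from 0.0103 to -0.00845. Chromosome 9 from 95600001 to 95800000 went from 0.0129 to -0.00509, and chromosome 18 from 44800001 to 45000000 went from 0.0136 to -0.00433. The eigenvector and the scores may rest on the same libraries, so insulation calls in these bins are not independent evidence. In the bins of chromosomes 17, 13 and 3, 10 of 10 insulation bins of 20 kb were also called lower in knock-out. The bin of chromosome 9 had 9 of 10 called lower, and the bin of chromosome 18 had 0 of 10. Among bins that turned positive, chromosome 9 from 49200001 to 49600000 went from -0.0226 to 0.00438, chromosome 11 from 9200001 to 9600000 from -0.0173 to 0.00595 and chromosome 13 from 109800001 to 110000000 from -0.0178 to 0.00311. Insulation was called higher in 3 of 20, 0 of 20 and 5 of 10 bins of these. The mean score of the chromosome 11 bins was lower in knock-out, at 0.0607 against 0.110 in wildtype, and 0 of its 20 bins were called lower.

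Insulation scores moved in opposite directions in the positive and negative compartments. Bins whose eigenvector was positive in both genotypes rose from 0.0937 ± 0.00357 in wildtype to 0.130 ± 0.00524 in knock-out (SD, n = 2), and 19.0% of these 56248 bins were called higher against 4.37% called lower. Bins negative in both genotypes went from -0.214 ± 0.00607 to -0.264 ± 0.00179 (SD, n = 2), and 17.8% of these 58246 bins were called lower against 3.68% called higher. The mean difference was above 0 in the positive compartment on 20 of 20 chromosomes and below 0 in the negative compartment on 20 of 20. Means over all bins were nearly level, at -0.0632 and -0.0652 in wildtype and -0.0691 and -0.0741 in knock-out. With level means, a rise in the positive compartment goes with a fall in the negative, so these directions are not separate results. Whether insulation rose or fell in absolute terms cannot be read from such scores. In the 831 bins of 20 kb that turned from negative to positive, the mean score differed by 0.0740 and 28.4% were called higher. In the 1607 that turned from positive to negative it differed by -0.0492 and 20.3% were called lower. The eigenvector and the scores may rest on the same libraries, so joint changes of both are not independent evidence.

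The gap between the compartments was 0.301 and 0.315 in the wildtype libraries and 0.396 and 0.391 in the knock-out libraries. Its difference of 0.0858 exceeded the range within either genotype, 0.0136 in wildtype and 0.00488 in knock-out. On each of the 20 chromosomes both knock-out libraries had a wider gap than both wildtype libraries, by 0.0493 on chromosome 13 to 0.109 on chromosome 14. The two-sided exact permutation test gave p = 0.333, the smallest possible. Across bins the wildtype eigenvector correlated with the difference in insulation with r = 0.446 and rho = 0.470. In single pairs of a knock-out with a wildtype library r was from 0.370 to 0.436, against 0.122 for the difference of the wildtype libraries and -0.0326 for that of the knock-out libraries. By decile of the wildtype eigenvector the mean difference ran from -0.0818 in the most negative to 0.0492 in the ninth and 0.0460 in the most positive.

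**Figure D3:**
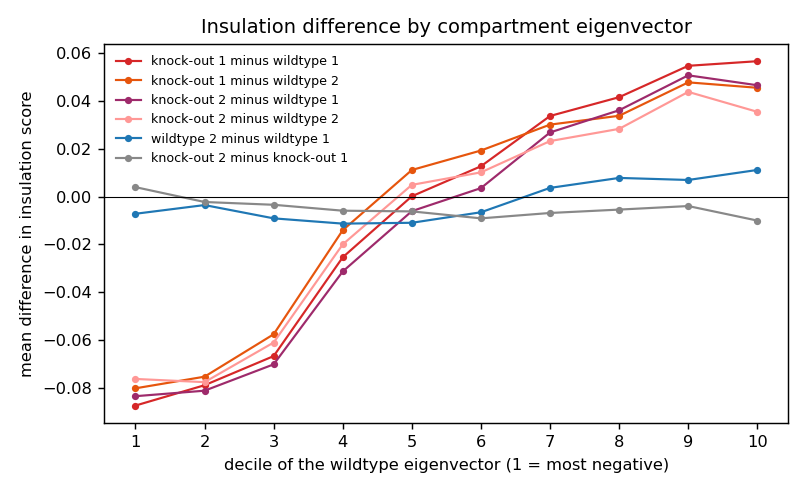
Mean difference in insulation score (vertical axis, score units) of 20 kb bins in each decile of the wildtype eigenvector (horizontal axis, 1 the most negative), with a line for each pair of libraries. The 4 lines of knock-out minus wildtype lie between -0.0874 and -0.0762 in decile 1 and between 0.0354 and 0.0566 in decile 10, whereas the lines within a genotype stay between -0.0113 and 0.0111.

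At 10 kb, the single profile of each genotype differed in the same direction as the single libraries in nearly all called bins. Wildtype and knock-out correlated with r = 0.974 over 227822 bins, with differences from -0.571 to 0.430. The difference at 10 kb correlated with that at 20 kb with r = 0.939. Of 25490 called bins of 20 kb that the 10 kb profiles cover, 25447 (99.8%) differed in the same direction. The mean difference at 10 kb was 0.0344 in bins of the positive and -0.0462 in bins of the negative compartment. These profiles may rest on the same libraries, so they are not independent evidence.

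Chromosome 6 of knock-out replicate 2 stood apart from the other 3 libraries. In 2 stretches of 440 kb, from 23440001 to 23880000 and from 57060001 to 57500000, its score lay below the lowest other library by more than 0.3 in each of 22 bins. The mean gap was -0.557 in the first stretch and -0.646 in the second. At the bin from 23620001 to 23640000 knock-out replicate 2 had a score of -0.972, against -0.0304 in knock-out replicate 1 and -0.0813 and -0.0166 in wildtype. At the bin from 57340001 to 57360000 it had -0.862, against 0.00574 in knock-out replicate 1 and 0.0374 and 0.113 in wildtype. Limma called 0 bins of the first stretch and 3 of the second. Over the genome 71 bins set this library apart by more than 0.3, of which 46 lay on chromosome 6. The other libraries had 8 such bins in wildtype replicate 1, 12 in wildtype replicate 2 and 29 in knock-out replicate 1. The regions named on chromosome 6 lie outside both stretches. Without knock-out replicate 2 limma called 31223 bins over the genome, 15490 higher and 15733 lower.

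**Figure D4:**
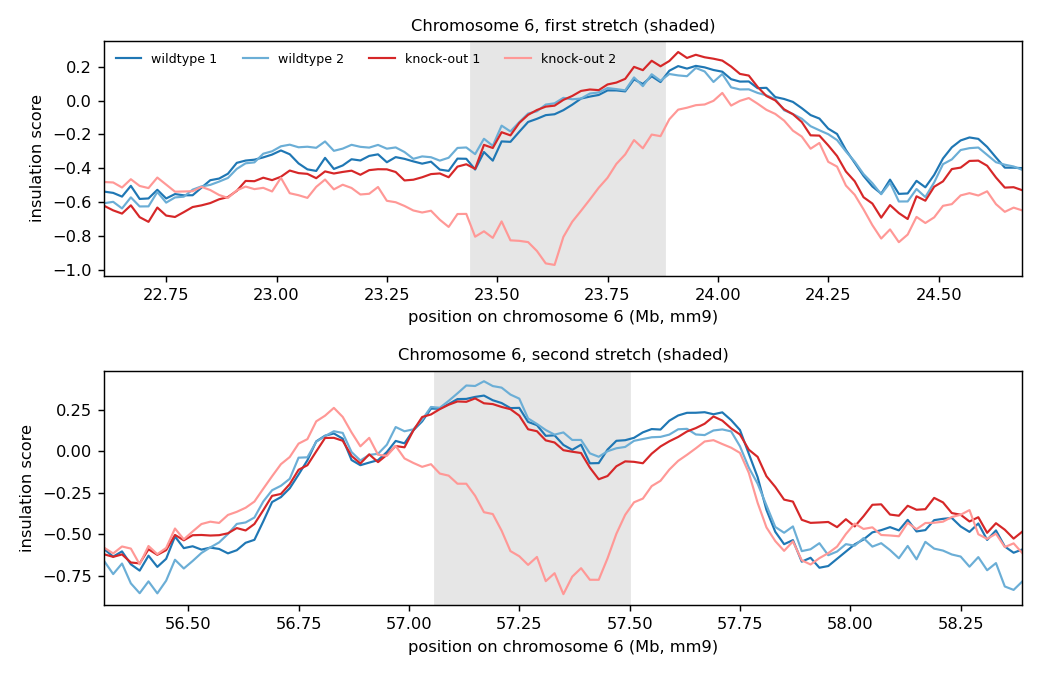
Insulation score (vertical axis, score units) of the 4 libraries along 2 parts of chromosome 6 (horizontal axis, Mb in mm9). In the shaded stretches, from 23440001 to 23880000 and from 57060001 to 57500000, knock-out replicate 2 falls to -0.972 and -0.862, below the other 3 libraries in each bin.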

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

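Subtracting a running mean over 51 bins, limma on boundary depths, unit SD scaling at the same boundaries, crossed library pairs and autosomes alone for the agreement between libraries, 10 kb profiles and all alternatives of the compartment gap except the filter on small eigenvector values were chosen after seeing the data. The other alternatives were fixed before the data were examined. Called bins numbered 26308, with 13148 higher and 13160 lower in knock-out. Quantile normalization, unit SD scaling, eBayes without trend and autosomes alone gave from 20739 to 27281 bins. Similar counts did not mean the same bins. Of the 26308 calls, 16868 were shared under quantile normalization, 20559 under unit SD scaling, 21257 without trend and 25573 on autosomes alone. With the T1 suffix as a block, which is also the replicate block by accession order, limma called 26772 bins (12929 higher, 13843 lower), of which 24739 were shared with the fit without it. All 4 titles carry R1, which pairs no libraries, and the difference of the wildtype libraries correlated with that of the knock-out libraries with r = -0.0551 across bins, so the block was kept as an alternative. The planned mean of 5 bins, 100 kb at this resolution, called 6035 of 23623 bins, 2952 higher and 3083 lower, since fewer bins were tested. A threshold of 0.1 called 39793 bins, 20859 of them lower, by construction. After the running mean was subtracted limma called 0 bins (0 higher, 0 lower; 21852 at an unadjusted p below 0.05, lowest adjusted p 0.0969), and the difference in SD reversed to -0.00508. The cause was not tested. Leaving out each library gave from 9213 to 31223 called bins, 4811 to 15490 higher and 3872 to 15733 lower. The counts fell by over 1.5 times without wildtype replicate 1 (9213, of which 8718 shared) and without wildtype replicate 2 (9445, of which 8894 shared). Of the 20 named regions, 20 kept their direction under every alternative run on them. The block, eBayes without trend and autosomes alone leave these differences unchanged by construction. The regions were chosen for large changes in these same libraries, so they could hardly reverse. They lost the call in most bins in 20 after subtraction, 4 without wildtype replicate 1, 3 without wildtype replicate 2 and 1 without knock-out replicate 1. After subtraction their differences were from -0.268 to -0.0317 in lower and from 0.0681 to 0.277 in higher regions, with mean standard errors from 0.0286 to 0.0747, against at most 0.0739 before. Subtraction removes by construction much of a change as broad as its window. The difference in SD stayed between 0.0168 and 0.0291 with a library left out and was 0.0221 in the 10 kb profiles. The difference in mean boundary depth ran from -0.0389 without knock-out replicate 2 to -0.00625 without knock-out replicate 1. It was -0.00172 with boundaries of the knock-out profile, where 49.1% were shallower in knock-out, and -0.0381 with those of the wildtype profile, where 72.3% were. It was -0.0414 with depths of at least 0.5 (69.7% of 532 shallower). With unit SD scaling it was -0.0785 SD (70.6% of 2608) and, at the same 1905 boundaries, -0.0979 SD (74.2%), part of which follows from dividing every depth by the larger SD of the knock-out libraries. After scaling, these differences exceeded the largest range within a genotype, 0.0388 SD and, at the same 1905 boundaries, 0.0464 SD. The difference with wildtype minima exceeded the largest range there, 0.0333. Under the other depth, window and profile settings the difference stayed below the range of the knock-out libraries. Taking minima from a profile favours that profile by construction. Limma on depths called 33 boundaries, 39 with the block and from 0 to 10 with a library left out (0 without knock-out replicate 1 or 2, with 277 and 408 at an unadjusted p below 0.05, 7 without wildtype replicate 1, 10 without wildtype replicate 2). Leaving out eigenvector values under 0.01 left 0 bins of different sign and 0 that turned negative, since 262 of 262 held such a value. The compartment gap difference stayed between 0.0790 and 0.0926 with a library left out and was 0.152 after scaling to unit SD. Leaving out libraries was not possible for the eigenvector, given as 1 profile per genotype. Alternatives for gene lists were not run, because no gene positions on mm9 were used here. Depth was unknown, so its effect was not assessed.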

Other observations

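The tests of the chromosome 6 stretches, of independent noise and of other splits of the libraries were chosen only after the result was seen. Scores far from boundaries were lower in both knock-out libraries, and near boundaries the change was mainly in knock-out replicate 1. The distances were compared with no test. The 9525 bins within 40 kb of a boundary had a mean difference of 0.0218, with 11.8% called higher and 4.77% lower in knock-out. Their mean score was -0.481 and -0.475 in wildtype, -0.440 in knock-out replicate 1 and -0.472 in knock-out replicate 2. The 47540 bins at 420 kb or more from any boundary had a mean difference of -0.0311, with 9.58% called higher and 16.9% lower. Their mean score was 0.0496 and 0.0488 in wildtype and 0.0175 and 0.0187 in knock-out. Bins from 60 to 400 kb away had means of 0.00890 and 0.00452 in the nearer and the farther of 2 classes. The eigenvector change of a 200 kb bin correlated with the insulation change of its 20 kb bins with r = 0.280 across bins. Each eigenvector value was repeated over its 20 kb bins. Both measures may rest on the same libraries, so shared noise could add to this correlation. Per chromosome, both the narrowest gap increase between compartments (0.0493) and the smallest ratio of SDs (1.004) were those of chromosome 13. That chromosome also had the lowest correlation of eigenvectors (0.990) and the narrowest gaps in wildtype, at 0.165 and 0.173. A narrow increase there need not be small relative to the gap.

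The first pattern is the rise of scores in the positive and their fall in the negative compartment in knock-out. A single amplitude factor per library would vanish after scaling to unit SD, but the gap still differed by 0.152, against a range within a genotype of at most 0.0337. Noise that is independent between libraries would give uncorrelated differences, whereas disjoint pairs of libraries correlated with r = 0.637. The T1 suffix falls on 1 library of each genotype. A difference in sequencing depth, in read filters or in the cell types left after lineage depletion stays open and untested, as does an effect of Stag2 loss on contacts within compartments.

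The second pattern is the pair of stretches of chromosome 6 in which knock-out replicate 2 fell below the other libraries. Unscored sequence nearby does not account for it, since 0% of the 44 bins lie within 200 kb of an unscored bin, against 2.82% of all bins. A rearrangement of chromosome 6 in the animal or cells of that library, with breakpoints 33.72 Mb apart, may give a pair of like dips, and their profiles over 500 kb on each side correlated with r = 0.878. Of 400 pairs of either profile with the 200 deepest other dips of that library 47 (11.8%) correlated as highly, so the shape leaves the question open. Contacts between the stretches, which would show a rearrangement directly, were not analysed here.

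The third pattern is that wildtype replicate 1 had scores in 742 bins of chromosome X that the other 3 libraries lacked, of 1235 such bins in all. The other libraries left at least 1.28 times as many bins unscored on X and from 1.06 to 1.13 times as many on autosomes. A deeper library or a looser filter that acts alike on all chromosomes would give like ratios, and the values lie between that and the ratio set in advance against it, so it cannot be told apart from an effect on X. No biological explanation was tested. Only bins scored in all 4 libraries entered the comparisons.

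The 4 libraries can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The split by genotype, 1 of the 3, gave 26308 called bins and the highest of the others gave 0, with at most 452 bins at an unadjusted p below 0.05 in limma. The other splits mix the genotypes within each group, so the difference between genotypes counts there as spread. Few calls then follow by construction, and these counts do not show whether the calls arose by chance.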
